A study of Mus musculus with 34 samples.

How the data were processed

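RNA was extracted from liver and sequenced by the submitters, who deposited 2 tables of processed values, for 22 and 12 libraries. Per the labels, the reads were processed with bcl2fastq, DRAGEN, STAR, Subread featureCounts and edgeR against the mouse build GRCm38; versions, settings and the order of steps are not used here. The deposited values are log2 CPM (log2 of the reads of a gene per M reads of the library) with a small prior count added by the authors. The values themselves show no further scaling between libraries. Each table has 55774 rows for 55487 gene IDs, since 287 rows repeat an ID with the same values, and 1 row per ID was kept. Of the IDs, 99.4% are in GENCODE mouse release M21, from which chromosome, start and end were taken.

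Whole read numbers were recovered from the log2 values, which gives the depth per library: 35.5 to 54.0 M in the first table, except 10.2 M in WT PBS 2, and 34.3 to 47.8 M in the second. With a tolerance of 0.1 read, 100% of the values checked in every library were whole. Those checked were of genes with low read numbers, and higher values were rounded to whole reads without this check. A gene with no read in any library of a group could lie at the lowest value of the table, and fold changes against such values depend on the prior count.

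Groups were taken from the sample titles. For 3 of the tunicamycin libraries the title and the column name do not match by number, so these are named by group only. The replicate numbers were tested for pairing and do not pair libraries: the deviations of libraries with the same number were not correlated across all numbers in any comparison.

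Genes were tested if their value was above 0 (1 CPM) in at least 5 libraries of the first table or 6 of the second, which kept 13468 and 13388 genes. The test was limma 3.58.1 (lmFit and eBayes with a trend) in R 4.3.3, two-sided, with all libraries of a table in 1 fit and Benjamini-Hochberg adjustment over the genes tested within each comparison, at a threshold of 0.05. There were 4 comparisons named by the series' design and 1 secondary comparison, of PiZ p50KO with WT PBS. The comparisons, the filter, the test, 35 gene lists and the rule for named genes were fixed before the data were examined.

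The rule names, for each comparison, the 6 genes with the greatest rise and the 6 with the greatest fall among those past the threshold whose groups do not overlap, with a mean of at least 2 log2 CPM in the higher group and no predicted gene names. For each list described it names up to 3 members past the threshold with the greatest change, and if none passed, the 1 with the greatest change. Of the genes so named, 2 are not reported here. It also names Nfkb1, the mouse Serpina1 genes and, for the overlaps, up to 4 genes per combination of directions. Other values of single libraries, such as those of WT TNFa 4 and of the libraries labelled PiZ p50KO, were chosen after they were seen.

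Gene lists with at least 5 measured members were tested against other genes with camera at a preset correlation of 0.01, and again with an estimated correlation, adjusted over the lists: 34 lists in the first table and 33 in the second. Camera called 17 lists higher and 5 lower in PiZ, 18 and 1 after TNFa, 11 and 14 in PiZ p50KO against PiZ, and 5 and 18 after tunicamycin. Without WT PBS 2 it called 13 higher and 11 lower in PiZ, 9 and 2 after TNFa, and 12 and 12 in PiZ p50KO against PiZ. With an estimated correlation 1, 2, 1 and 0 lists passed with all libraries, 5, 2 and 3 without WT PBS 2, and 7, 5 and 5 without the 4 libraries named in the report. A called list whose median, mean and test differ in sign occurred 1 time in PiZ p50KO (circadian clock genes, median 0.07, mean -0.06, higher by camera with adjusted p = 0.0172 and adjusted p = 0.409 with an estimated correlation) and 2 times after tunicamycin. Those were the genes of gluconeogenesis and the urea cycle (median 0.05, mean -0.19, lower with adjusted p = 0.0446, and adjusted p = 0.582 with an estimated correlation) and the NRF2 list (median -0.10, mean 0.04).

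Overlaps were counted per direction beside the product of the 2 counts over the genes tested in both. Where comparisons share libraries, the covariance of the fold changes was set beside that of 100 simulated draws of unchanged groups. The procedure was tested on simulated data with the real spread of each group. With all libraries, the share of planted changes of 1, 2 and 4 log2 units recovered was 40.3%, 76.1% and 92.4% for PiZ, 40.3%, 76.1% and 93.9% for TNFa, 28.4%, 71.6% and 98.5% for PiZ p50KO, and 68.7%, 97.0% and 100% for tunicamycin, with 0 in the wrong direction. The report gives the unchanged genes called for each comparison. A list planted with a change of 1 was recovered in every comparison, with 0 other lists called.

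Alternatives planned were another pseudocount (1 CPM), no filter, a stricter filter (4 CPM), quantile normalization, a shift of libraries to the same median, robust moderation, library weights, fits to the compared groups only, blocking by replicate number and leaving out each replicate. For the overlap of PiZ and tunicamycin, a minimum absolute log2 fold change of 1 was also planned. Added after seeing the data were fits without WT PBS 2 for lists, overlaps and PiZ p50KO, fits without PiZ p50KO 1 and 2, without WT TNFa 4 and combinations of these, limma's voom on the recovered reads and, for PiZ p50KO against WT, the same settings as for the other comparisons. Principal components were taken from the log2 values of the genes tested, centred and not scaled. Positions of libraries between WT and PiZ are medians over 230 genes, those called in PiZ against WT with an absolute log2 fold change of at least 3, of the value's place between the mean of WT PBS without library 2 and the mean of PiZ. No column of the files was left unused.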

Results

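Messenger RNA levels were measured by sequencing in the livers of male mice of 3 months of age. PiZ mice carry a human gene for the Z variant of alpha-1 antitrypsin, a protease inhibitor secreted by hepatocytes that in this form polymerizes in the endoplasmic reticulum (ER). The 22 libraries of the first table come from 6 wild-type (WT) mice given the vehicle PBS, 6 WT mice 2 hours after TNFa, 5 PiZ mice given PBS and 5 PiZ mice labelled as knockouts of p50 (PiZ p50KO) given PBS. The 12 libraries of the second table come from 6 WT mice given the vehicle DMSO and 6 WT mice 24 hours after tunicamycin, a drug that blocks N-linked glycosylation. The labels place the tables in different batches, so no value was compared between a library of the first table and a library of the second. The tables hold no gene named SERPINA1, so the human transgene could not be measured.

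In the first table, WT PBS libraries 1 to 6 held 54.0, 10.2, 41.6, 43.7, 51.1 and 42.0 M reads, and WT TNFa libraries 1 to 6 held 42.4, 46.3, 47.3, 37.3, 41.1 and 38.9 M. PiZ libraries 1 to 5 held 46.1, 45.9, 48.6, 35.5 and 50.4 M, and PiZ p50KO libraries 1 to 5 held 52.3, 50.02, 39.0, 52.3 and 46.4 M. In the second table, WT DMSO libraries 1 to 6 held 35.2, 35.9, 34.3, 36.9, 43.8 and 39.3 M, and the 6 tunicamycin libraries held between 38.8 and 47.8 M. The library labelled WT PBS 2 stood apart: 72.2% of its reads lay on protein-coding genes, against 97.3% to 97.8% in the other 21 libraries of the table. It had 32360 genes above 1 CPM (reads per M reads of the library), against 11683 to 13202, and its Alb (albumin) level was 12.22 log2 CPM, against 15.43 to 16.49. It was kept in the comparisons, as planned. Total counts and several list counts are also given without it; leaving out each library in turn was planned for the totals, and its use for the lists was chosen after seeing the data. In what follows, ± after a log2 fold change is its standard error and ± after a mean is the standard deviation. The p-values of single genes were adjusted over all genes tested. They weigh a difference against the spread between libraries and assume that each library is a separate mouse. Those of gene lists (camera) were adjusted over the lists and weigh the members of a list against the other genes. Over all genes tested, the median log2 fold change was 0.25 for PiZ, -0.15 for TNFa, -0.22 for PiZ p50KO against PiZ and 0.38 for tunicamycin. Shifting every library to the same median left 0.03, 0.07, 0.04 and -0.07. Without WT PBS 2 and without that shift, the median was 0.41 for PiZ and -0.016 for TNFa. Both medians with all libraries thus depend on WT PBS 2. Its own median over the genes tested was 4.85 log2 CPM, against 3.04 to 3.33 in the other WT PBS libraries, and the shift moves it too. A gene's change is best read against the median of the same fit.

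Nfkb1, the gene of p50 (chromosome 3, 135584655 to 135691547), varied between libraries with the same label. Its level was 3.92 to 4.34 log2 CPM in WT PBS libraries 1 and 3 to 6, and 6.68 in WT PBS 2. It was 6.57 to 6.95 in 5 of the WT TNFa libraries and 4.77 in WT TNFa 4. It was 4.62 to 5.58 in the 5 PiZ libraries. Among the libraries labelled PiZ p50KO it was 4.51 and 4.86 in libraries 1 and 2, and 3.31, 3.74 and 3.37 in libraries 3 to 5. Nfkb1 transcripts were therefore present in every library labelled PiZ p50KO, and the labels do not say which part of the gene is deleted.

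**Figure D1:**
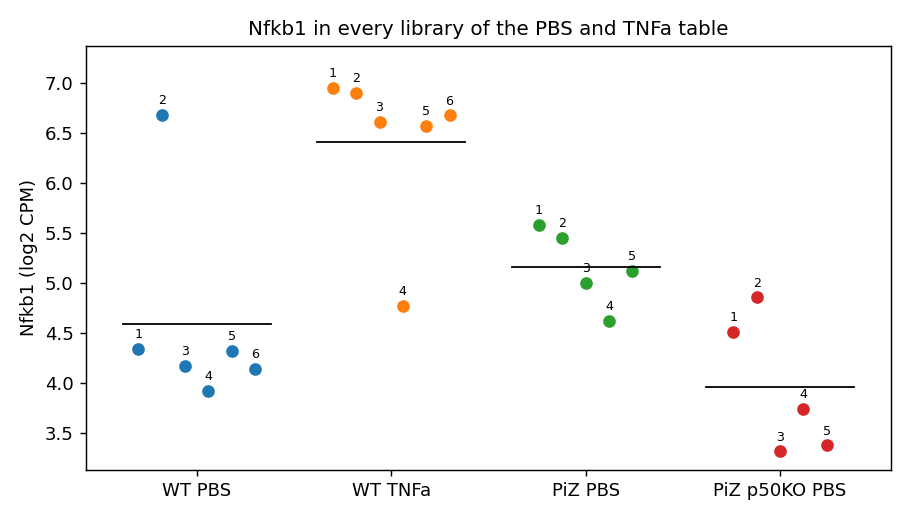
Nfkb1 level in log2 CPM (vertical axis) in each of the 22 libraries of the first table, by labelled group (horizontal axis). Points are libraries with their number and lines are group means; PiZ p50KO 3 to 5 lie between 3.31 and 3.74, and PiZ p50KO 1 and 2 at 4.51 and 4.86.

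The comparison of PiZ with WT livers, both given PBS, asks which transcripts differ in a liver that makes the Z variant. Slamf7, an immune cell receptor, was at 4.99 ± 0.29 log2 CPM in PiZ (n = 5) and -3.35 ± 3.81 in WT (n = 6), and Serpina3f, a protease inhibitor, at 10.33 ± 0.27 and 2.38 ± 1.72. With them rose 19 of 23 ER chaperones, 22 of 25 macrophage markers, 20 of 28 matrix markers, 22 of 32 interferon-stimulated genes and 15 of 31 cell cycle genes (in this order, adjusted p = 0.375, 0.0158, 0.329, 0.329 and 0.466 with an estimated correlation). When WT PBS 2 was left out, the macrophage list no longer passed with an estimated correlation (adjusted p = 0.0757) and the cell cycle list did (adjusted p = 0.00723). Gdpd3, a phospholipid-metabolising enzyme, was at -3.26 ± 0.89 in PiZ and 3.63 ± 0.56 in WT, the greatest fall among the genes named by the rule.

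In all, 2037 genes rose and 299 fell of 13468 tested, or 6152 and 831 without WT PBS 2. The preponderance of rises depended on the scaling: 1019 rose and 687 fell after shifting libraries to the same median, and 1087 and 982 after quantile normalization; with the same shift and without WT PBS 2, 2362 rose and 3058 fell. The libraries of the 2 groups did not overlap for 1462 of the 13468 genes, where chance gives 0.433% of genes, and 1264 of these were called. The 6 greatest rises of this kind were in Samd3 (log2 fold change 8.64 ± 1.51, adjusted p = 0.000393), Slamf7 (8.33 ± 1.5, 0.000511), Spink1 (7.99 ± 1.43, 0.000493), Serpina3f (7.95 ± 0.96, 9.35e-06), Wfdc16 (7.94 ± 1.26, 0.000153) and Ly6d (7.34 ± 1.05, 5.49e-05). Samd3 had no read in 5 of the 6 WT libraries, Wfdc16 in 4, Spink1 in 3 and Slamf7 in 2, so their fitted folds depend on the small count the authors added and are no bounds. The 6 greatest falls were in Gdpd3 (-6.90 ± 1.34, 0.000988), Sbk2 (-6.10 ± 1.16, 0.000833), Camk2b (-5.64 ± 0.96, 0.000298), Rfx4 (-5.49 ± 1.01, 0.000607), Clec2h (-5.47 ± 1.21, 0.00288) and Rims4 (-4.92 ± 1.14, 0.00423). On GRCm38, Serpina3f lies on chromosome 12 at 104214544 to 104221129 and Gdpd3 on chromosome 7 at 126766334 to 126775649. Nfkb1 did not pass the test (0.56 ± 0.44, adjusted p = 0.457), but did without WT PBS 2 (0.98, adjusted p = 0.021).

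Of 23 measured ER chaperones and folding enzymes, 19 rose and 0 fell (21 and 0 adjusted over the list alone), with a median log2 fold change of 1.49; without WT PBS 2 the median was 0.93 with 20 rising. Creld2 and Sdf2l1, both induced by misfolded protein in the ER, rose by 2.42 ± 0.56 and 2.23 ± 0.39, and Fkbp11, a peptidyl-prolyl isomerase of the ER, by 2.07 ± 0.33. The list was higher than other genes (camera adjusted p = 4.01e-08; adjusted p = 0.375 with an estimated correlation). With all libraries, WT PBS 2 among them, shifted to the same median, 3 of its members were called. The list's median was then 1.27 and it still passed camera (adjusted p = 2.6e-05). Of 27 genes of ER-associated degradation and the translocon, 19 rose and 0 fell (23 and 0 adjusted over the list alone; camera adjusted p = 2.56e-07, and adjusted p = 0.329 with an estimated correlation); 1 was called after the same shift, with a list median of 0.58 (0.80 before) and camera adjusted p = 0.00113. Among them Derl3, a component of the degradation channel, rose by 4.34 ± 0.74, Ssr3 of the translocon by 1.61 ± 0.37 and Edem2, which acts on misfolded glycoproteins, by 1.23 ± 0.26. Of 26 genes of the PERK-ATF4-CHOP arm, which raises amino acid supply under stress, 11 rose and 0 fell (13 and 0 adjusted over the list alone), and 18 rose without WT PBS 2. The cystine transporter Slc7a11 rose by 5.03 ± 1.29, asparagine synthetase Asns by 4.08 ± 1.04 and Psat1 of serine synthesis by 3.65 ± 0.93. This list had camera adjusted p = 0.00208, and adjusted p = 0.448 with an estimated correlation.

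Of 33 NF-kB target genes, 13 rose and 0 fell (20 and 0 adjusted over the list alone), and 28 rose without WT PBS 2. The chemokines Cxcl2, Ccl2 and Cxcl10 rose by 4.44 ± 1.16, 4.06 ± 0.83 and 3.31 ± 0.82. The list's camera adjusted p was 3.43e-05, and adjusted p = 0.526 with an estimated correlation. Of 32 interferon-stimulated genes, 22 rose and 0 fell (28 and 0 adjusted over the list alone), led by the antiviral enzymes Oas1a (3.78 ± 0.61) and Oas2 (3.02 ± 0.95) and by Usp18, a brake on interferon signalling (2.75 ± 0.54). Its camera adjusted p was 7.53e-11, and adjusted p = 0.329 with an estimated correlation.

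Of 25 Kupffer cell and macrophage markers, 22 rose and 1 fell (23 and 1 adjusted over the list alone), with Gpnmb at 5.23 ± 1.01, Itgax at 4.15 ± 0.82 and lysozyme Lyz2 at 3.21 ± 0.39. The list passed camera with the preset (adjusted p = 2.91e-13) and, with all libraries, was the only list of this comparison to pass with an estimated correlation (adjusted p = 0.0158, and 0.0757 without WT PBS 2). A further 5 lists passed with an estimated correlation without WT PBS 2. The list of cell cycle genes was higher (adjusted p = 0.00723). Lower were those of xenobiotic metabolism (adjusted p = 0.00723), the mouse Serpina1 genes (0.010), PPAR-alpha and fatty acid oxidation (0.0438) and male-biased liver genes (0.0454). Of 29 xenobiotic genes 10 fell and 3 rose in that fit, also when adjusted over the list alone, and of 19 male-biased genes 9 fell and 2 rose (10 and 2 adjusted over the list alone). With all libraries 3 and 3 of the xenobiotic genes did, with a median of 0.40 (adjusted p = 0.819 with an estimated correlation), and 3 and 2 of the male-biased genes (adjusted p = 0.54). Of 28 extracellular matrix and stellate cell markers, 20 rose and 0 fell (23 and 0 adjusted over the list alone; camera adjusted p = 5.65e-13, and adjusted p = 0.329 with an estimated correlation). Timp1, an inhibitor of matrix-degrading proteases, rose by 5.08 ± 0.97, and the fibrillar collagens Col1a1 and Col3a1 by 3.58 ± 0.57 and 3.23 ± 0.27. Of 31 cell cycle genes, 15 rose and 0 fell (22 and 0 adjusted over the list alone), and 31 rose without WT PBS 2. Cyclin B gene Ccnb1 rose by 5.67 ± 1.202, the proliferation marker Mki67 by 4.21 ± 1.07 and the spindle gene Tpx2 by 4.15 ± 1.19 (list camera adjusted p = 1.03e-06, and adjusted p = 0.466 with an estimated correlation, or 0.00723 without WT PBS 2).

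The mouse Serpina1 genes, the counterparts of the human gene, lie together on chromosome 12 between 103728156 and 103958975, and their near-identical copies share reads, so their separate levels are uncertain. None passed the test in PiZ (Serpina1a -0.26 ± 0.53, Serpina1b -0.03 ± 0.56, Serpina1c -0.15 ± 0.60, Serpina1d -0.24 ± 0.36, Serpina1e -0.66 ± 0.86). Serpina1a (-0.91), Serpina1b (-0.67), Serpina1c (-0.92) and Serpina1d (-0.58) fell without WT PBS 2. Of the 72 called genes named by the rule for this comparison, 45 showed no overlap between the libraries of the groups, and 67 did not when WT PBS 2 was set aside. On simulated data with the real spread of each group, the fit to all libraries called 109 of 13245 unchanged genes, and 15 without WT PBS 2. The fit to all libraries recovered 27 of 67, 51 of 67 and 61 of 66 planted changes of 1, 2 and 4 log2 units. Unchanged genes were thus a far larger share of its simulated calls than the adjusted p threshold allows. The simulation drew the spread of WT PBS anew for every one of its libraries, whereas in the data much of that spread comes from WT PBS 2 alone. It therefore cannot tell whether the PiZ calls with WT PBS 2 hold more false ones than their adjusted p states. The share among the real calls was not measured.

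TNFa, a cytokine that acts through NF-kB, was compared with PBS in WT mice to show the acute response of the liver. Within 2 hours, 26 of 33 NF-kB targets rose (adjusted p = 0.0374 with an estimated correlation). Cxcl10, a chemokine, was at 8.84 ± 1.47 log2 CPM after TNFa (n = 6) and -0.07 ± 1.46 after PBS (n = 6), and Tlr2, a receptor for bacterial lipoproteins, at 7.69 ± 1.46 and 1.01 ± 0.53. Of 30 acute-phase genes 12 rose, and of 15 neutrophil markers 6 did (adjusted p = 0.0517 and adjusted p = 0.145 with an estimated correlation). Ppp1r3c, which promotes glycogen synthesis, fell from 5.50 ± 0.56 to 2.81 ± 1.13.

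In all, 294 genes rose and 253 fell, or 1026 and 541 without WT PBS 2, and 548 and 523 after shifting libraries to the same median. The groups did not overlap for 249 of the genes tested, where chance gives 0.216% of genes, and 122 of these were called. The 6 greatest rises of this kind were in Cxcl10 (8.91 ± 0.78, adjusted p = 1.62e-06), Ccl2 (7.26 ± 0.79, 7.85e-06), Tlr2 (6.67 ± 0.63, 1.81e-06), Ch25h (6.20 ± 0.99, 0.000665), Rnd1 (6.19 ± 0.59, 1.81e-06) and Ripk2 (5.94 ± 0.60, 3.47e-06). Ch25h had no read in 2 of the WT PBS libraries. The 6 greatest falls were in Ppp1r3c (-2.70 ± 0.44, 0.000786), Ccn1 (-1.98 ± 0.33, 0.00109), Gucy1b1 (-1.96 ± 0.41, 0.00689), Pde7b (-1.87 ± 0.49, 0.0309), Ackr4 (-1.75 ± 0.34, 0.0034) and Tsc22d1 (-1.62 ± 0.24, 0.000311). The fall of Pde7b was -1.22 without WT PBS 2, in which it was at 5.91, against 1.89 to 2.30 in the other WT PBS libraries. For Gucy1b1, Ackr4 and Ripk2, WT PBS 2 also lay far from the rest of WT PBS, so their folds depend on that library too. Cxcl10 lies on chromosome 5 at 92346638 to 92348889. WT TNFa 4 had Cxcl10 at 5.84 and Ccl2 at 2.61, against 9.25 to 9.60 and 5.78 to 6.51 in the other TNFa libraries. On the second principal component without WT PBS 2 (18.5% of the variance) it lay at -16.4, against 55.6 to 57.5 in the other TNFa libraries and -44.2 to -31.7 in WT PBS. Its Cxcl10 and Ccl2 still lay above those of every WT PBS library (at most 2.58 and -0.87). WT TNFa 4 thus differed from WT PBS in the direction of the other TNFa libraries, but by less. The size of its response to TNFa is therefore in doubt, and it is included in the means and folds given here. Leaving out WT TNFa 4 alone gave 875 genes, leaving out WT TNFa 1, 2, 3 or 6 gave 308, 314, 297 and 327, and leaving out both WT PBS 2 and WT TNFa 4 gave 2120. On simulated data the fit to all libraries called 126 of 13245 unchanged genes, and 14 without WT PBS 2. The fit to all libraries recovered 27 of 67, 51 of 67 and 62 of 66 planted changes of 1, 2 and 4 log2 units. Unchanged genes were thus a far larger share of its simulated calls than the adjusted p threshold allows. What this says of the TNFa calls with WT PBS 2 has the same limit as for PiZ, since the simulation spread the difference of WT PBS 2 over all WT PBS libraries.

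NF-kB genes were the list furthest from the other genes. Of 33 NF-kB targets, 26 rose and 0 fell (30 and 0 adjusted over the list alone), with a median log2 fold change of 3.20; all 33 rose without WT PBS 2. Cxcl10 and Ccl2 are members, and Cxcl2, another chemokine, rose by 8.01 ± 1.11. All 5 genes of NF-kB subunits rose, over all genes and adjusted over the list alone: Relb by 4.21 ± 0.74, Nfkb2 by 3.01 ± 0.54, Rela by 2.07 ± 0.27 and Nfkb1 by 1.82 ± 0.42 (adjusted p = 0.0143) among them. These 2 lists passed camera with the preset correlation (adjusted p = 7.52e-50 and 2.3e-10) and were the only ones in this comparison to pass with an estimated correlation with all libraries (adjusted p = 0.0374 and 0.0427) and without WT PBS 2 (adjusted p = 0.0461 for both). Nfkb1, Nfkb2, Rel and Relb are members of both lists, so the 2 results are not independent. The lists of acute-phase genes, neutrophil markers and interferon-stimulated genes passed too when WT PBS 2, WT TNFa 4 and PiZ p50KO 1 and 2 were left out (adjusted p = 0.0178, 0.0298 and 0.0435 with an estimated correlation).

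Of 30 acute-phase genes, which the liver secretes in inflammation, 12 rose and 0 fell (14 and 0 adjusted over the list alone; camera adjusted p = 4.83e-21, and adjusted p = 0.0517 with an estimated correlation). Il1rn, the receptor antagonist of interleukin 1, rose by 5.13 ± 0.65, the iron-sequestering Lcn2 by 4.83 ± 0.58 and the metallothionein Mt2 by 4.71 ± 1.12. Of 15 neutrophil markers, 6 rose and 0 fell (10 and 0 adjusted over the list alone), and 12 rose without WT PBS 2. Ngp rose by 5.51 ± 1.05, S100a9 by 4.09 ± 0.86 and Retnlg by 3.85 ± 0.84; Ngp had no read in 2 WT PBS libraries. The neutrophil list had camera adjusted p = 1.88e-13, and adjusted p = 0.145 with an estimated correlation. Of 21 immediate early genes, 4 rose and 1 fell (10 and 2 adjusted over the list alone; 8 and 1 without WT PBS 2): Maff rose by 2.60 ± 0.55 and Ier3 by 2.42 ± 0.67, while Ccn1, a matrix-associated signalling protein, fell. That list had camera adjusted p = 0.00567, and adjusted p = 0.6 with an estimated correlation.

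Of 32 interferon-stimulated genes, 5 rose and 0 fell after TNFa (7 and 0 adjusted over the list alone), and 11 rose without WT PBS 2. The guanylate-binding genes Gbp5 and Gbp2 rose by 4.22 ± 0.66 and 2.31 ± 0.38, and Tap1, a peptide transporter for antigen presentation, by 1.29 ± 0.32. The list had camera adjusted p = 2.85e-05, and adjusted p = 0.552 with an estimated correlation. Of 15 genes of bile acid synthesis and transport, 0 rose and 2 fell, also when adjusted over the list alone. These were Nr0b2, a repressor of bile acid synthesis (-3.20 ± 0.73), and Cyp7a1, its rate-limiting enzyme (-2.63 ± 0.67); the list did not pass camera (adjusted p = 0.0738). Of 23 ER chaperones, 1 rose and 0 fell (1 and 0 adjusted over the list alone; 2 and 0 without WT PBS 2), namely Hyou1 (1.17 ± 0.33). That list had camera adjusted p = 8.22e-08, and adjusted p = 0.413 with an estimated correlation. Of the 40 called genes named by the rule, 16 showed no overlap between groups, and 25 did not when WT PBS 2 was set aside. Serpina1 genes a to e did not pass the test, with log2 fold changes from -0.07 ± 0.82 in Serpina1e to 0.66 ± 0.51 in Serpina1a. For Serpina1a, Serpina1b, Serpina1c and Serpina1d, WT PBS 2 lay far from the rest of WT PBS, so their folds depend on that library.

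The comparison of the libraries labelled PiZ p50KO with PiZ asks which transcripts of the PiZ liver differ when p50, a DNA-binding subunit of NF-kB, is missing. In the livers labelled PiZ p50KO, 10 of 28 matrix markers, 9 of 25 macrophage markers and 2 of 31 cell cycle genes fell (in this order, adjusted p = 0.277, 0.0391 and 0.409 with an estimated correlation). Ubd, a ubiquitin-like protein induced in inflammation, was at -1.29 ± 0.46 log2 CPM (n = 5) against 3.68 ± 0.40 in PiZ (n = 5). Vnn1, a pantetheinase, was at 4.59 ± 0.84 against 1.17 ± 0.29, and Cyp8b1, an enzyme of bile acid synthesis, at 8.73 ± 0.28 against 6.34 ± 0.23.

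The libraries labelled PiZ p50KO did not form 1 group. On a scale where 230 genes chosen for their difference between PiZ and WT give a median of 0 in WT and 1 in PiZ, libraries 1 and 2 lay at 0.144 and 0.126, and libraries 3 to 5 at 0.520, 0.764 and 0.696. Gdpd3, at -3.26 ± 0.89 in PiZ, was at 3.55 and 3.11 in PiZ p50KO 1 and 2, and Sbk2, at -2.38 ± 0.56 in PiZ, at 2.99 and 3.39. Samd3, at 3.71 ± 0.24 in PiZ, was at -2.99 and -3.46 in them. The total and the list counts of this comparison are therefore also given without 4 libraries, namely these 2, WT PBS 2 and WT TNFa 4, an alternative chosen after seeing the data. Its genes without overlap between groups were counted with all libraries.

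**Figure D2:**
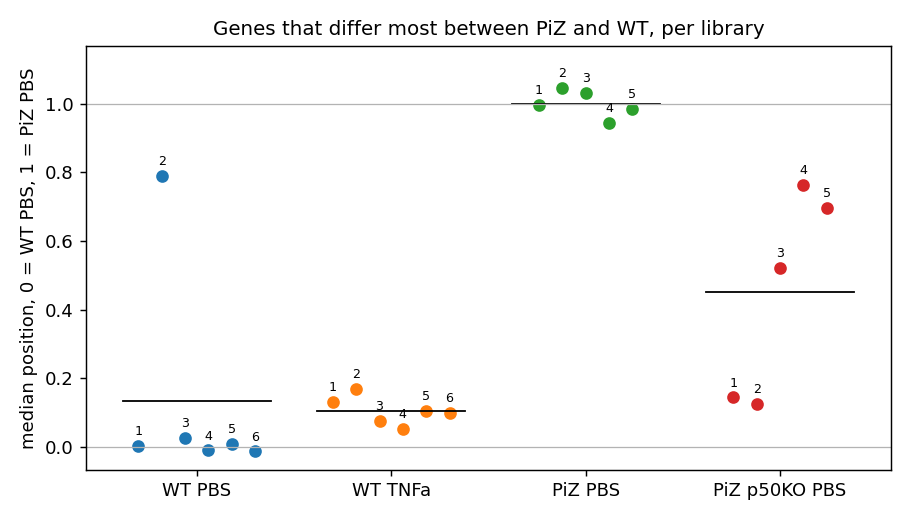
Median position of 230 genes between WT PBS (0) and PiZ PBS (1) (vertical axis) for each of the 22 libraries of the first table, by labelled group (horizontal axis). Points are libraries with their number and lines are group means; the genes were chosen on the WT and PiZ libraries, which lie near 0 and 1 by construction except WT PBS 2 (0.788), and PiZ p50KO 1 and 2 lie at 0.144 and 0.126.

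In all, 69 genes rose and 399 fell. Without WT PBS 2, which enters through the shared estimate of the spread, the counts were 451 and 2910, and without the 4 libraries 227 and 1467. On simulated data with the real spread of each group, the fit to all libraries called 10 of 13246 unchanged genes, and the fit without WT PBS 2 called more, 57 of 13245. The fit without WT PBS 2 recovered 43 of 67, 62 of 67 and 66 of 66 planted changes of 1, 2 and 4 log2 units. Unchanged genes were thus a larger share of its simulated calls than the adjusted p threshold allows. The preponderance of falls depended on the scaling: 125 rose and 243 fell after shifting libraries to the same median, and 212 and 272 after quantile normalization; with the same shift and without WT PBS 2, 1333 rose and 1214 fell. The groups did not overlap for 1836 of the genes tested, where chance gives 0.794% of genes, and 372 of these were called. Among the 6 greatest rises of this kind were those of Vnn1 (3.42 ± 0.39, adjusted p = 2.51e-05), Cyp2c37 (2.78 ± 0.63, 0.0155), Glt1d1 (2.40 ± 0.27, 1.84e-05), Cyp8b1 (2.39 ± 0.33, 0.000329) and Pctp (2.39 ± 0.27, 2.51e-05). The 6 greatest falls were in Vmn2r3 (-6.53 ± 1.75, 0.0411), Sprr1a (-5.86 ± 1.37, 0.0193), Tinag (-5.23 ± 1.42, 0.043), Ubd (-4.97 ± 0.78, 0.00106), Psmc3ip (-4.78 ± 1.07, 0.0142) and Tmprss4 (-4.39 ± 1.03, 0.0203). Vmn2r3 had no read in 2 of the libraries labelled PiZ p50KO, and Sprr1a and Tinag in 1 each. Without the 4 libraries, these folds were -4.10 for Vmn2r3, -3.64 for Sprr1a and -3.37 for Tinag. Ubd lies on chromosome 17 at 37193892 to 37196095. Leaving out PiZ 1, 2, 3 or 5 gave 234, 185, 194 and 281 genes, leaving out PiZ p50KO 1 or 2 gave 209 each, and leaving out both of these gave 94.

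Nfkb1 itself did not pass the test between the libraries labelled PiZ p50KO and PiZ (-1.195 ± 0.46, adjusted p = 0.176). It did without WT PBS 2 (-1.195, adjusted p = 0.0145) and without the 4 libraries (-1.68, adjusted p = 7.44e-06). Of the 5 genes of NF-kB subunits, 0 rose and 0 fell (0 and 4 adjusted over the list alone), and Relb, the greatest change, was at -1.98 ± 0.81 with adjusted p = 0.212. The subunit list had camera adjusted p = 0.0172, and adjusted p = 0.415 with an estimated correlation; without WT PBS 2 it no longer passed (adjusted p = 0.0605, with 3 falling), and without the 4 libraries 4 fell. Of 33 NF-kB targets, 0 were called, also when adjusted over the list alone, with a median of -1.27; the chemokine Ccl7 was at -3.06 ± 1.04 with adjusted p = 0.115. As a list these targets were lower than other genes (camera adjusted p = 0.000747, and adjusted p = 0.578 with an estimated correlation), and 9 fell both without WT PBS 2 and without the 4 libraries. Serpina1e, whose reads are shared with its near-identical copies, rose by 3.52 ± 0.89 (adjusted p = 0.0305), with levels of 13.14, 13.30 and 9.56 in PiZ p50KO 3 to 5, 7.67 and 7.46 in PiZ p50KO 1 and 2, and 5.58 to 7.50 in PiZ. Without the 4 libraries the rise was 5.29.

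Of 28 extracellular matrix and stellate cell markers, 10 fell and 0 rose (21 and 0 adjusted over the list alone), and 25 fell without WT PBS 2 and 20 without the 4 libraries. The collagens Col1a1, Col3a1 and Col1a2 fell by 2.82 ± 0.60, 2.41 ± 0.29 and 2.34 ± 0.53. The list had camera adjusted p = 6.33e-14, and adjusted p = 0.277 with an estimated correlation. Of 25 Kupffer cell and macrophage markers, 9 fell and 0 rose (19 and 0 adjusted over the list alone), and 23 fell without WT PBS 2 and 15 without the 4 libraries. Timd4, a marker of resident Kupffer cells, fell by 2.09 ± 0.52, Lyz2 by 1.59 ± 0.40 and the lysosomal marker Cd68 by 1.53 ± 0.27; without the 4 libraries Lyz2 fell by 0.81. This list passed camera with the preset (adjusted p = 2.5e-11) and, with all libraries, was the only one here to pass with an estimated correlation (adjusted p = 0.0391; 0.0966 without WT PBS 2 and 0.0799 without the 4 libraries). The cell cycle list was lower with an estimated correlation without WT PBS 2 (adjusted p = 0.00536), and the lists of xenobiotic metabolism (0.00536) and the mouse Serpina1 genes (0.00443) were higher. Of 29 xenobiotic genes 9 rose and 1 fell in that fit (9 and 3 adjusted over the list alone), and all 5 Serpina1 genes rose. Without the 4 libraries these 3 lists passed (adjusted p = 0.00211, 0.002 and 0.00193), as did those of bile acid synthesis and transport (0.019) and male-biased liver genes (0.0115), both higher. With all libraries 2 of the xenobiotic genes rose and 0 fell, and the adjusted p with an estimated correlation was 0.415 for that list and 0.22 for the Serpina1 genes.

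Of 31 cell cycle genes, 2 fell and 0 rose (13 and 0 adjusted over the list alone), and 29 fell without WT PBS 2 and 23 without the 4 libraries. Cyclin D gene Ccnd1 fell by 2.28 ± 0.37 and the replication licensing gene Mcm5 by 1.32 ± 0.34. The list had camera adjusted p = 1.38e-07, and adjusted p = 0.409 with an estimated correlation (0.00536 without WT PBS 2 and 0.00211 without the 4 libraries). Of 26 genes of the PERK-ATF4-CHOP arm, 3 fell and 0 rose (12 and 0 adjusted over the list alone): Trib3, an inhibitor of AKT, by 2.56 ± 0.68, the amino acid transporter subunit Slc3a2 by 1.27 ± 0.24 and Eif2ak3, the gene of PERK, by 0.97 ± 0.26. Trib3 and Eif2ak3 no longer passed without the 4 libraries (-1.75, adjusted p = 0.081, and -0.76, adjusted p = 0.109). This list had camera adjusted p = 0.000615, and adjusted p = 0.381 with an estimated correlation; without WT PBS 2, 13 of its genes fell, and without the 4 libraries 5 did and it no longer passed (adjusted p = 0.106). Of 23 ER chaperones, 0 were called (2 fell adjusted over the list alone), with Fkbp11 at -1.17 ± 0.34 and adjusted p = 0.0636, and the list did not pass camera (adjusted p = 0.247). Without WT PBS 2 the list passed camera with the preset (adjusted p = 0.0355), with 9 chaperones falling, but not with an estimated correlation. Without the 4 libraries it did not pass camera (adjusted p = 0.115), with 3 falling. Of the 30 called genes named by the rule, 24 showed no overlap between the libraries of the groups.

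As a secondary comparison, the libraries labelled PiZ p50KO were set against WT PBS, which differ in both the transgene and the label of the knockout. With limma, 11 genes rose and 1 fell, 1115 had an unadjusted p under 0.05, and voom on the recovered reads called 33. Quantile normalization called 0 (1265 at an unadjusted p under 0.05), as did limma without WT PBS 3, 5 or 6 or PiZ p50KO 4 or 5, each left out alone, so these 12 calls depended on single libraries. Without WT PBS 2 the count was 1562, without PiZ p50KO 1 and 2 it was 327, and without the 4 libraries 2670. Nfkb1 was at -0.63 ± 0.44 (adjusted p = 0.817), and fell without the 4 libraries (-0.70, adjusted p = 0.00984).

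Tunicamycin was compared with DMSO in WT mice as a drug-induced ER stress. All 23 ER chaperones rose, as did 22 of 24 genes of the PERK-ATF4-CHOP arm (adjusted p = 0.314 with an estimated correlation for both lists). Atf3, a stress-induced transcription factor, was at 9.59 ± 2.11 log2 CPM after tunicamycin (n = 6) and 0.10 ± 0.57 after DMSO (n = 6), and Nupr1, another stress-induced regulator, at 7.58 ± 1.04 and -0.45 ± 0.68. Of 20 lipogenesis genes 14 fell, and of 38 proteins secreted by hepatocytes 24 (adjusted p = 0.314 with an estimated correlation for both). Glul, glutamine synthetase, fell from 9.33 ± 0.20 to 4.59 ± 0.19, and Thrsp, a lipogenic regulator, from 8.50 ± 0.85 to 3.11 ± 0.78.

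In all, 6067 genes rose and 1802 fell of 13388 tested. The preponderance of rises depended on the scaling: 3233 rose and 3913 fell after shifting libraries to the same median, and 3534 and 3547 after quantile normalization. The groups did not overlap for 4452 of the genes tested, where chance gives 0.216% of genes, and 4435 of these were called. The 6 greatest rises of this kind were in Vmn2r3 (10.50 ± 0.44, adjusted p = 7.83e-09), Sprr1a (9.81 ± 1.09, 1.45e-05), Akr1b7 (9.63 ± 0.73, 8.43e-07), Atf3 (9.50 ± 0.76, 1.29e-06), Wfdc3 (9.01 ± 0.94, 9.29e-06) and Nupr1 (8.02 ± 0.44, 6.78e-08). Vmn2r3 had no read in 4 of the DMSO libraries and Sprr1a in 2, so their fitted folds are no bounds. The 6 greatest falls were in Chrna4 (-6.77 ± 0.69, 7.91e-06), Hsd3b5 (-5.48 ± 0.79, 9.95e-05), Thrsp (-5.39 ± 0.41, 9.02e-07), Tbx3os1 (-4.89 ± 0.74, 0.000133), Ces1d (-4.80 ± 0.47, 5.33e-06) and Glul (-4.74 ± 0.13, 5.78e-11). Atf3 lies on chromosome 1 at 191170296 to 191218039, and Glul on the same chromosome at 153899944 to 153909723. Nfkb1 did not pass the test (-0.01 ± 0.14, adjusted p = 0.954). On simulated data the fit called 10 of 13165 unchanged genes.

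The tunicamycin library with 47.8 M reads stood apart from the other 5. Its Atf3 level was 5.70 log2 CPM, against 9.21 to 11.30, and its Cxcl10 level 0.81, against 3.49 to 5.88. On the first principal component (69.3% of the variance) it lay at 5.59, against 40.3 to 105.9 in the other tunicamycin libraries and -83.8 to -56.6 in DMSO. Its Glul level, 4.80, was close to the 4.38 to 4.76 of the others. It is included in the means and folds given here. Without it, 6118 genes rose and 2027 fell, and the rises of Atf3 and Cxcl10 were 10.27 and 4.42.

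All 23 ER chaperones and folding enzymes rose, also when adjusted over the list alone, with a median log2 fold change of 2.68: Fkbp11 by 5.62 ± 0.33, Creld2 by 5.54 ± 0.50 and Sdf2l1 by 4.17 ± 0.42. Of 27 genes of ER-associated degradation and the translocon, 26 rose and 0 fell, also when adjusted over the list alone. Derl3 rose by 7.55 ± 0.47, the ubiquitin ligase Syvn1 by 3.77 ± 0.37 and its partner Herpud1 by 3.24 ± 0.56. Of 24 genes of the PERK-ATF4-CHOP arm, 22 rose and 0 fell, also when adjusted over the list alone, among them Atf3, Nupr1 and Psat1 (7.61 ± 0.34). Of 30 genes of N-glycosylation, the pathway that tunicamycin blocks, 28 rose and 0 fell (29 and 0 adjusted over the list alone). Gfpt1, which makes the precursor of the sugar donor, rose by 3.47 ± 0.42, the mannosyltransferase Alg12 by 2.32 ± 0.27 and Ost4, a subunit of the oligosaccharyltransferase, by 2.14 ± 0.37. These lists had camera adjusted p = 1.17e-12, 7.28e-10, 2.1e-07 and 2.18e-09 in this order, each with adjusted p = 0.314 with an estimated correlation, with which no list of this comparison passed.

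Of 20 lipogenesis genes, 14 fell and 1 rose (15 and 1 adjusted over the list alone), with Srebf1, the transcription factor of the pathway, at -3.23 ± 0.45 and acetyl-CoA carboxylase Acacb at -2.96 ± 0.25 beside Thrsp. Of 38 proteins secreted by hepatocytes, 24 fell and 1 rose, also when adjusted over the list alone: the apolipoprotein Apoa1 by 2.47 ± 0.36, the complement component C4b by 2.05 ± 0.33 and transthyretin Ttr by 1.89 ± 0.25 were the greatest falls. These lists had camera adjusted p = 7.08e-11 and 2.13e-13, and adjusted p = 0.314 with an estimated correlation for both. Serpina1a, Serpina1b, Serpina1c and Serpina1d fell by 1.17 ± 0.29, 1.16 ± 0.23, 1.22 ± 0.27 and 1.38 ± 0.26, with the same limit on reads shared between copies. Serpina1e did not pass (-1.08, adjusted p = 0.0662), but did without the tunicamycin library with 47.8 M reads (-1.30, adjusted p = 0.0308) and without WT DMSO 2 (-1.51, adjusted p = 0.00166). Of 25 NF-kB targets, 6 rose and 5 fell (6 and 4 adjusted over the list alone): Cxcl10 rose by 3.72 ± 0.74 and Nfkbib, an inhibitor of NF-kB, by 1.49 ± 0.25, and Tnfaip2 fell by 1.51 ± 0.35. That list did not pass camera (adjusted p = 0.0663), and its median (-0.01) and mean (0.21) differ in sign. Of the 56 called genes named by the rule, 43 showed no overlap between groups.

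**Figure D3:**
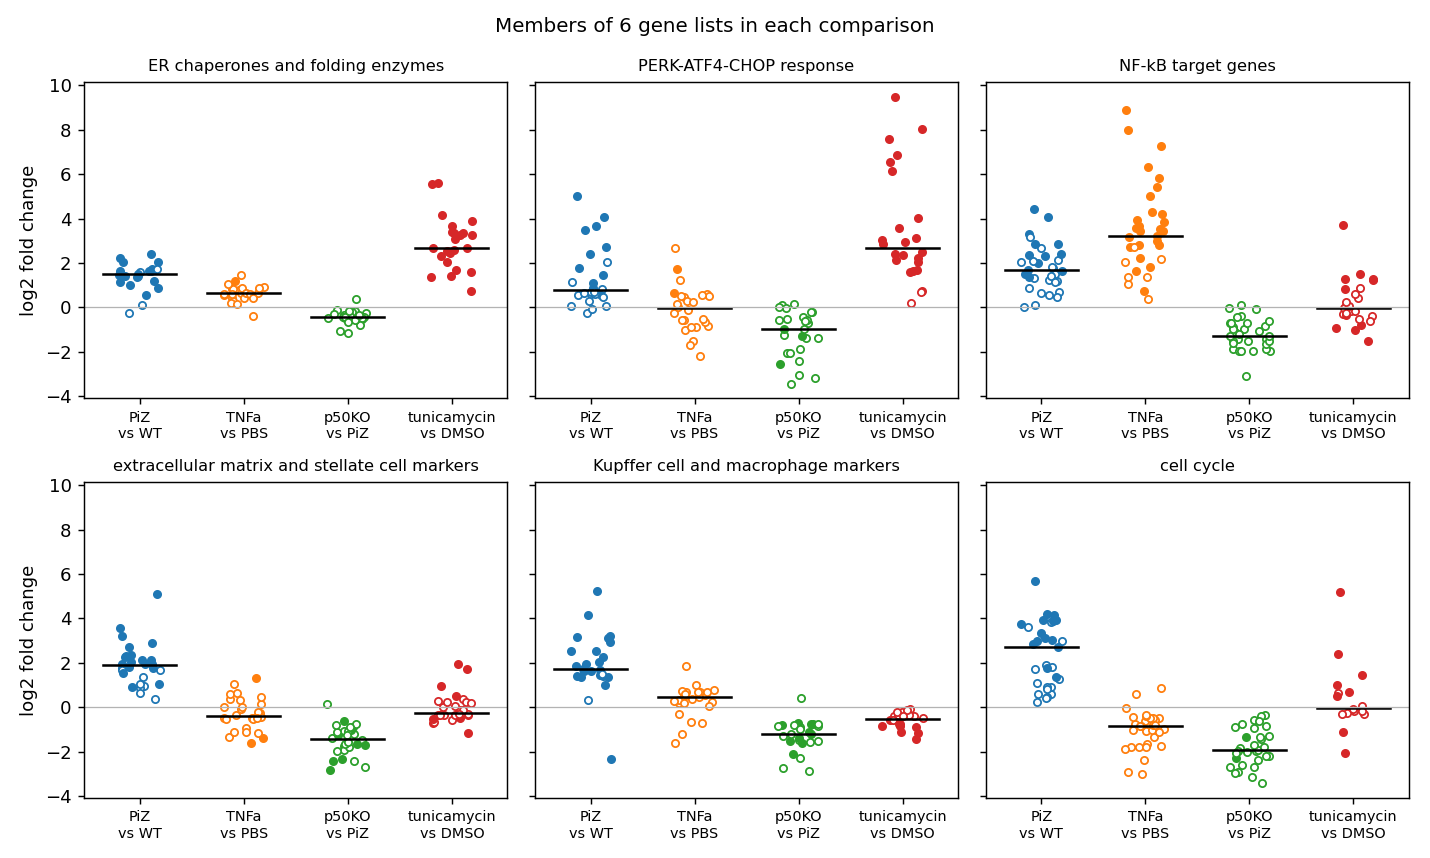
Log2 fold change (vertical axis) of each measured member of 6 gene lists in the 4 comparisons (horizontal axis), with all libraries. Filled points passed adjusted p of 0.05, open points did not, and lines are list medians; the ER chaperones have medians of 1.49 in PiZ and 2.68 after tunicamycin, and the NF-kB targets 1.68 in PiZ and 3.20 after TNFa.

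The next comparison asks whether genes that changed in PiZ are those that tunicamycin changed. Among 12620 genes tested in both tables, 1024 rose in both, where independence gives 845, and 142 fell in both, where it gives 39.4. A further 212 rose in PiZ and fell after tunicamycin (257 by independence), and 52 the reverse (130). Vmn2r3 (8.38 ± 1.68 in PiZ), Sprr1a (6.83 ± 1.31), Wfdc3 (6.52 ± 1.52) and Slc7a11 rose in both, and Clec2h, Cnmd (-3.69 ± 0.57 and -3.34 ± 0.43), Slc13a2 (-2.81 ± 0.45 and -3.06 ± 0.55) and Dct (-2.66 ± 0.40 and -3.19 ± 0.40) fell in both. Vmn2r3 had no read in 5 WT PBS libraries and Wfdc3 in 3. Serpina9 (3.40 ± 0.51 and -3.55 ± 0.78), Ntrk2 (5.16 ± 1.26 and -2.26 ± 0.39), Ces1b (2.18 ± 0.52 and -2.91 ± 0.37) and Mki67 (4.21 ± 1.07 and -2.05 ± 0.43) rose in PiZ and fell after tunicamycin. AI506816, Ces4a, Ttll11 and Cyp17a1 fell in PiZ, by 2.64 to 3.99, and rose after tunicamycin, by 2.20 to 3.66. Across genes, which are not independent replicates, Pearson's r of the fold changes was 0.227 and Spearman's rho 0.151. With libraries shifted to the same median, 205 rose in both (203 by independence) and 335 fell in both (198). The excess of shared rises was thus not seen under that scaling. With this shift 336 rose in PiZ and fell after tunicamycin (252), and 80 did the reverse (159). After quantile normalization 279 rose in both (244) and 378 fell in both (253), with 297 (257) and 131 (240) in the 2 opposite directions. The deficit of genes that rose in PiZ and fell after tunicamycin thus depended on the scaling. Without WT PBS 2, 2924 rose in both (2519 by independence) and 405 fell in both (111).

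The genes of PiZ and TNFa were compared in the same way, with the limit that both use the WT PBS libraries. Of 13468 genes, 132 rose in both, where independence gives 44.5, and 11 fell in both (5.62); 10 rose in PiZ and fell after TNFa, and 0 the reverse. Elf3, an epithelial transcription factor (5.14 ± 1.00 in PiZ and 5.19 ± 0.96 after TNFa), Lcn2 (6.65 ± 0.61 and 4.83 ± 0.58), Cxcl2 and Ccl2 rose in both. Ppp1r3g (-2.99 ± 0.95 and -4.52 ± 0.91), Mfsd2a (-4.10 ± 0.69 and -2.78 ± 0.66), G0s2, an inhibitor of lipolysis (-2.68 ± 0.90 and -3.85 ± 0.86), and Dntt (-2.48 ± 0.51 and -1.93 ± 0.49) fell in both. Psmc3ip, Fam124a, Sowahb and Tpbgl rose in PiZ, by 1.37 to 3.11, and fell after TNFa. Shared controls alone give overlap: simulated unchanged groups gave a covariance of 0.285 between the fold changes and up to 64 shared genes in 100 draws, against a real covariance of 0.20 and 143 genes. Without WT PBS 2 the real covariance was 0.269 against 0.0397; 753 genes rose in both (469 by independence) and 28 fell in both (33.4). With WT PBS 1 to 3 for PiZ and 4 to 6 for TNFa, 40 rose in both (34.6 by independence) and 1 fell in both (1.08). In the reverse arrangement 104 rose in both (53.8) and 9 fell in both (27.2), while 220 rose in PiZ and fell after TNFa (304), with a covariance of -0.257. When WT PBS 2 was also set aside, 398 rose in both (259) and 9 fell in both (10.1) in the first arrangement, and 292 (173) and 3 (9.56) in the second, with covariances of 0.226 and 0.222.

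Genes that changed in PiZ were followed into the libraries labelled PiZ p50KO. Of the genes that rose in PiZ, 381 fell in PiZ p50KO against PiZ (60.3 by independence), and 61 that fell in PiZ rose (1.53), 442 in all, with 0 changing in the same direction. Vmn2r3, Sprr1a, Tinag (6.53 ± 1.36 in PiZ) and Ubd (5.42 ± 0.75) rose in PiZ and fell in PiZ p50KO. Moxd1 (-6.40 ± 1.53 and 5.82 ± 1.60), Slc39a2, a zinc transporter (-5.39 ± 0.72 and 4.56 ± 0.75), Rfx4 and Vnn1 (-3.63 ± 0.37 and 3.42 ± 0.39) did the reverse. Rfx4 did not pass in PiZ p50KO without the 4 libraries (2.56, adjusted p = 0.0605). Moxd1 had no read in 3 of the PiZ libraries and Slc39a2 in 2. The PiZ libraries enter both comparisons with opposite sign, which favours opposite directions by chance: the covariance was -0.508, against -0.0358 in simulated unchanged groups. With PiZ 1 to 3 in the first comparison and 4 to 5 in the other, or the reverse, it was -0.464 and -0.449, with 22 and 177 reversed genes. Without WT PBS 2, PiZ p50KO 1 and PiZ p50KO 2, 1192 rose in PiZ and fell in PiZ p50KO (603 by independence), 170 did the reverse (13.9), 8 rose in both and 15 fell in both, with a covariance of -0.376.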

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

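The test of WT PBS 2 as a shallow library, the exon length trend of the other 21 libraries, the 4 tests of PiZ p50KO 1 and 2 (wrong label, 2 of a swap, low depth), the test of genes near Nfkb1 and the fits that leave out doubted libraries were chosen only after the result, or values close to it, had been seen.

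A single library lay far from the rest of its group for several measures, where chance does so in about 1 in 20 groups. WT PBS 2 held 10.2 M reads (41.6 to 54.0 M in the other WT PBS libraries), had 32360 genes above 1 CPM (11683 to 12045) and had 72.2% of its reads on protein-coding genes (97.4% to 97.6%). Its median correlation with its group was 0.354 (0.965 to 0.979) and its Nfkb1 level 6.68 (3.92 to 4.34). Nfkb1 was 4.77 in WT TNFa 4 (6.57 to 6.95). The share of mitochondrial reads was 19.4% in PiZ p50KO 3 (7.55% to 8.67%), 23.4% in WT DMSO 2 (4.35% to 5.59%) and 8.24% in WT tunicamycin 1 (3.57% to 4.51%), and WT DMSO 2 had a median correlation with its group of 0.928 (0.979 to 0.984). Of the named genes, 1 library lay far from the rest of its group for 49 of 104 in WT PBS (WT PBS 2 for 47), 23 of 45 in WT TNFa (WT TNFa 4 for all 23), 9 of 96 in PiZ (PiZ 4 for 8), 2 of 39 in PiZ p50KO, 9 of 58 in WT DMSO (WT DMSO 2 for 7) and 7 of 58 after tunicamycin (the library with 47.8 M reads for 4).

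WT PBS 2 stands apart from the other WT PBS libraries, with 268105 reads on 9644 of the 18232 genes that have no read in the other 21 libraries. Shallow depth alone is argued against: the other WT PBS libraries thinned to its depth reached at most 37.0% of its number of genes above 1 CPM. Reads from genomic DNA or unspliced RNA and RNA of another tissue cannot be told apart by the tests made. Across those genes its reads increase with exon length (Spearman's rho across genes 0.419), which passed the bound set beforehand for genomic DNA or unspliced RNA. A check added later found that across all genes the reads of the other 21 libraries increase with length too (at least 0.555). Such a trend is thus not particular to WT PBS 2, though that check did not use the same set of genes. For RNA of another tissue, the top 5% of the genes with no read in the other 21 libraries held 45.7% of the reads on them, between the bounds set for either answer. Of the reads of WT PBS 2, 16.0% lay on genes annotated as TEC and 3.01% on those annotated as lincRNA. In the other 21 libraries these shares were at most 0.0702% and 0.152%. Its share of mitochondrial reads was 0.832%, against 5.05% to 20.3% in the others. No bound was set for these shares, so they were not used to decide. The design gives no biological explanation for a single library, and none was tested.

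PiZ p50KO 1 and 2 stand apart from PiZ p50KO 3 to 5, whose medians between WT and PiZ were 0.520, 0.764 and 0.696. Low depth is argued against, with at least 50.02 M reads in both. Of their reads, 97.6% and 97.7% lay on protein-coding genes, but this share does not measure degradation, which was not tested. A wrong label, or a sample from outside the PiZ groups, may account for it: their medians between WT (0) and PiZ (1) were at most 0.144, and their Nfkb1 at least 4.51, above the 3.92 to 4.34 of WT PBS 1 and 3 to 6. A swap of both with WT PBS or WT TNFa libraries is argued against, since the second highest median among those was 0.169; a swap of 1 of them with WT PBS 2, at 0.788, cannot be told apart because that library is in doubt itself, though its Serpina3f, at -0.999, was far below the 9.05 to 9.44 of PiZ p50KO 3 to 5. A real difference between mice with the same label stays open and was not tested.

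Genes near Nfkb1 on chromosome 3 were examined because a knockout can carry DNA of its founder strain around the deleted gene. Without the 4 doubted libraries, 29 of 170 tested genes within 25 Mb of Nfkb1 were called between the libraries labelled PiZ p50KO and PiZ, or 17.1%, against 12.5% of the 13287 others (Fisher's exact test p = 0.0804), a ratio of 1.36. By the same exact test, 8 of the 170 were called with all libraries (p = 0.393), and 56 without WT PBS 2 alone (p = 0.0200). Founder DNA and an effect of the knockout cannot be told apart by this ratio, which lies between the bounds set for either answer. The strain of the knockout is not in the labels.

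Among 100 splits of the same libraries, the real one included, 2 gave as many genes as PiZ against WT (2336, with 2696 the highest other) and 2 as many as TNFa against PBS (547, with 570 the highest other). For PiZ p50KO against PiZ and for tunicamycin, 1 split, the real one, gave as many (468 with 0 the highest other, and 7869 with 5182). Splits with as many genes were thus a share under 0.05 of those tried. Splits that mix the groups carry the difference between groups into the spread, which lowers their counts. The splits therefore bear only on a random assignment of libraries to groups, and do not give the cause of the counts. The split with 2696 genes kept only 1 of the 5 PiZ libraries in its first group. It had WT PBS 2 in the other part, with the remaining PiZ libraries. The split with 570 kept 5 of the 6 TNFa libraries, also with WT PBS 2 in the other part, so the counts also reflect the structure of the samples.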

How the results depend on the processing

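The fits with voom and without doubted libraries were alternatives added only after the data were seen, except that leaving out single libraries of the compared groups was planned. A minimum fold change was planned for the overlap of PiZ and tunicamycin, but not in combination with leaving out WT PBS 2. Among the libraries of the compared groups, leaving out WT PBS 2 moved the PiZ and TNFa counts by the greatest factor, and library weights and blocking by replicate number moved both by more. Over all alternatives, 0 of 350 results of the lists described and 0 of 5323 gene results changed direction while called in the main or the alternative fit. Part of this was fixed in advance: 38 of the 350 come from a list test without direction. Genes named because their groups do not overlap also could not change direction when a library was left out. Changes of sign in results called in neither fit were not counted. Of the results, 292 and 4860 kept their side of the threshold, 52 and 378 lost their call and 6 and 85 gained one. Of the 38 list results, 31 were lost with an estimated correlation.

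Leaving out each library of the 2 compared groups in turn gave 1648 to 6983 genes for PiZ, 297 to 1567 for TNFa, 185 to 521 for PiZ p50KO against PiZ and 6929 to 8789 for tunicamycin. The low end for TNFa was without WT TNFa 3 and for PiZ p50KO without PiZ 2; the high ends for PiZ and TNFa were without WT PBS 2. The tunicamycin count of 7869 stayed within 1.5 times under every setting tried.

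For PiZ, TNFa and PiZ p50KO against PiZ in this order, the counts were 1439, 317 and 192 without a filter, 9522, 3079 and 4847 with library weights, and 1142, 152 and 2250 with only the compared groups. With the replicate numbers as a block, though they do not pair the libraries, they were 430, 85 and 1050. A median shift gave 1071 for TNFa. Recovered reads with voom gave 3911 for PiZ and 1336 for PiZ p50KO (659 for TNFa), and 7096, 1429 and 3748 without WT PBS 2. PiZ p50KO against PiZ gave 3361 without WT PBS 2. A median shift without that library gave 5420 for PiZ and 1835 for TNFa, and quantile normalization 5280 and 1603. The counts were 7385, 2425 and 1694 without the 4 libraries, 2120 for TNFa without WT PBS 2 and WT TNFa 4, 94 for PiZ p50KO without PiZ p50KO 1 and 2, and 1492 without these and WT PBS 2. PiZ p50KO against WT, 12 with all libraries, gave 33 with voom, 0 with quantile normalization, with only the compared groups and with a block, 1 without a filter, 2 with the pseudocount and with robust moderation, 31 with the stricter filter and 5749 with library weights. Leaving out single libraries gave 123 without PiZ p50KO 1, 103 without PiZ p50KO 2, 2 without WT PBS 1 or 4, 3 without PiZ p50KO 3, and 0 without WT PBS 3, 5 or 6 or PiZ p50KO 4 or 5. It gave 1562 without WT PBS 2 (1194 with voom, 1020 with a median shift, 582 with quantile normalization), 327 without PiZ p50KO 1 and 2, 2464 without these 3 and 2670 without the 4.

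Overlaps grow with the lengths of the lists, so the counts here do not by themselves measure association. The overlap of PiZ and tunicamycin (1166) was 618 without a filter, 657 after quantile normalization, 540 after a median shift, 3329 without WT PBS 2, 3451 also without PiZ p50KO 1 and 2, 325 with a log2 fold change of at least 1, and 548 with that and without WT PBS 2. The overlap of PiZ and TNFa (143) was 53 without a filter, 781 without WT PBS 2, 924 also without PiZ p50KO 1 and 2, and 544 without WT PBS 2 after quantile normalization. It was 41 with PiZ against WT PBS 1 to 3, and without WT PBS 2 407 and 295 in the 2 arrangements. The reversed genes (442) were 180 without a filter, 3126 without WT PBS 2, 1362 also without PiZ p50KO 1 and 2, and 2361 without WT PBS 2 after quantile normalization. With PiZ 1 to 3 against WT they were 22, or 635 without WT PBS 2, and with PiZ 4 and 5 they were 177, or 2192 without WT PBS 2.

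Depth limits genes with few reads, for which folds depend on the prior count; at 10.2 M reads WT PBS 2 is the least precise library. Each left-out fit has fewer libraries, and a lost call there does not show the absence of a difference.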

Other observations

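The lists below were fixed in advance, and the fits without doubted libraries were chosen after the data were seen. In PiZ livers, of 28 genes of PPAR-alpha and fatty acid oxidation, 3 fell and 0 rose (2 and 0 adjusted over the list alone), and 13 fell and 3 rose without WT PBS 2. Vnn1, a pantetheinase under PPAR-alpha control, fell by 3.63 ± 0.37, the fatty acid hydroxylase Cyp4a10 by 2.03 ± 0.69 and the acyl-CoA thioesterase Acot1 by 1.98 ± 0.26 (list camera adjusted p = 0.000294, and adjusted p = 0.455 with an estimated correlation, or 0.0438 without WT PBS 2). Of 25 genes of the NRF2 response, 17 rose and 0 fell (18 and 0 adjusted over the list alone): the glutathione transferases Gstm3 and Gsta1 rose by 5.48 ± 0.67 and 3.74 ± 0.69, and Srxn1, which repairs peroxiredoxins, by 3.62 ± 0.37 (camera adjusted p = 1.34e-08, and adjusted p = 0.329 with an estimated correlation). Of 16 cholangiocyte and progenitor markers, 8 rose and 0 fell, also when adjusted over the list alone, with Anxa2 at 3.24 ± 0.43, Sox4 at 3.17 ± 0.73 and Prom1 at 2.56 ± 0.77 (camera adjusted p = 0.000491, and adjusted p = 0.398 with an estimated correlation); 13 rose without WT PBS 2.

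In PiZ p50KO against PiZ, 6 of these 16 cholangiocyte markers fell and 0 rose (10 and 0 adjusted over the list alone), and 12 fell without WT PBS 2 and 13 without the 4 libraries. Prom1 fell by 3.38 ± 0.81, Anxa2 by 2.47 ± 0.45 and Tspan8 by 2.25 ± 0.48 (camera adjusted p = 2.03e-07, and adjusted p = 0.277 with an estimated correlation). Of 25 genes of cholesterol synthesis, 0 were called, also when adjusted over the list alone, with Fdps at 1.16 ± 0.45; the list was higher than other genes (camera adjusted p = 2.6e-13, and adjusted p = 0.277 with an estimated correlation), and 10 rose without WT PBS 2 and 11 without the 4 libraries. After tunicamycin, 18 of these 25 genes fell and 3 rose, also when adjusted over the list alone. Nsdhl fell by 2.00 ± 0.21 and Stard4 by 1.95 ± 0.27 (camera adjusted p = 2.98e-10, and adjusted p = 0.314 with an estimated correlation). Of 20 macrophage markers, 9 fell and 0 rose after tunicamycin, also when adjusted over the list alone, with Gpnmb at -1.42 ± 0.48, Folr2 at -1.15 ± 0.33 and Mpeg1 at -1.11 ± 0.25 (camera adjusted p = 3.32e-06, and adjusted p = 0.314 with an estimated correlation). Of 24 NRF2 genes, 7 rose and 11 fell, also when adjusted over the list alone: Gsta1, the transporter Abcc4 and Srxn1 rose by 3.33 ± 0.78, 2.83 ± 0.29 and 2.64 ± 0.31. The NRF2 list had a median of -0.10, a mean of 0.04 and a lower direction in camera (adjusted p = 0.00822, and adjusted p = 0.369 with an estimated correlation).

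Transcripts of pancreatic enzymes varied between libraries of the same group. Cpa1, Prss2, Pnlip and Cel were at 8.65, 8.34, 9.31 and 8.36 log2 CPM in WT TNFa 5, at 6.71, 6.76, 7.46 and 6.79 in PiZ p50KO 4, at 4.85, 4.28, 5.60 and 4.51 in WT TNFa 6, and at 3.39, 3.26, 5.15 and 3.55 in PiZ p50KO 3. They were at 2.80 to 3.55 in PiZ p50KO 5, 2.59 to 3.11 in PiZ 5 and 1.74 to 4.15 in WT PBS 2. In the second table they were at 6.996, 7.08, 7.11 and 6.51 in 1 tunicamycin library and at 5.79, 5.66, 5.90 and 5.38 in tunicamycin 5. In 3 other tunicamycin libraries they lay between 1.56 and 3.39, in tunicamycin 1 they had no read, and in WT DMSO they were at most 1.73.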
